A study of Mus musculus with 18 samples.

How the data were processed

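Stranded mRNA libraries (KAPA kit, per the labels' protocols) of 18 samples were analysed, 6 from the CRISPR screen pool and 12 from clones. The authors deposited whole-number counts per Ensembl gene, 1 column per library, after alignment with STAR 2.7 to GRCm39 per the submitters' processing notes, which do not state the counting program, the annotation release or the strand setting. The authors also deposited a signal table in CPM (counts per M). Each deposited CPM value was checked to equal the count divided by a TMM-scaled library size after edgeR's filterByExpr, within 0.00447 CPM, over 15771 genes of the screen and 15529 genes of the clones. CPM in the text was recomputed from the counts in the same way. Each count table holds 56980 gene IDs, of which 52073 have a symbol, and 68 symbols are carried by more than 1 ID, for which the ID with the most counts was used.

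Library totals ranged from 14.8 to 21.7 M counts. A group at 0 counts was given a floor of 3 counts over the group, and a fold against it is a lower bound. For 1 to 3 counts the ratio is given with its 95% counting interval (exact binomial, Clopper-Pearson, converted to a ratio). Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The share of counts on the unnamed ID ENSMUSG00000119584 ranged from 0.481% to 5.32% in the screen and from 0.204% to 1.47% in the clones, and mitochondrially encoded genes held 2.57% to 5.17% and 0.599% to 0.861%.

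Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, TMM, filterByExpr), with Benjamini-Hochberg adjusted p under 0.05 and no fold minimum. The 6 screen libraries were fitted together with day as group. For genotype, the 3 libraries of a clone were summed first, because the clone is the unit that repeats a genotype, and 2 clones were tested against 2 (17914 genes). A fit of the 12 libraries in 4 clone groups gave the library-level values, and a gene was called shared by the clones when all 4 knockout clone against wild-type clone contrasts passed in the same direction. Standard errors are the log2 change divided by the square root of the F statistic. Named genes were those 10 with the largest rise and 10 with the largest fall among called genes with a mean of at least 5 CPM and the same direction in every pair of libraries (5 and 5 between clones of 1 genotype), without predicted genes. For genotype they were filled up from the genes shared by the clones. Of each gene list described, up to 4 members with the smallest p were named, and some are left out for length. Peds1 and its neighbor Ube2v1 were always named.

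Gene lists, 35 with 543 genes, covered states of pluripotency, neural and other lineages, regional identity, lipid metabolism, cell cycle, stress, signaling, imprinting and technical classes. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and a minimum of 4 tested members, adjusted over the lists of a comparison. With an estimated correlation 0 lists passed in the screen steps and the genotype comparison, against 11, 16 and 3 with the preset. At an unadjusted p under 0.05 the estimated correlation gave 2, 8 and 0 lists. The lists of any comparison whose result is not printed singly did not pass in the screen steps or between genotypes. The list members, the fits, the named-gene rule and most alternatives were fixed before the data were examined.

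Peds1 (older symbol Tmem189) and Ube2v1 overlap the annotated readthrough gene Gm20431. Gm20431 had 0 counts and Ube2v1 at most 5 counts in any library, so Peds1 counts come from the part of the gene that the counting could assign. Genes with near-identical copies, such as the Xlr and Zscan4 families, are uncertain one by one. Chromosomes came from the GENCODE vM21 annotation, which placed 17539 of the 17914 genes.

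The steps were tested on simulated counts for the real genes with 200 genes changed. For day 4 against day 0 of the screen (15301 genes), 56.7% of the genes changed 1.5-fold, 74.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 16 false calls. For wild-type clone 2 against clone 1 (15333 genes) the shares were 62.7%, 77.6% and 95.5%, with 8 false calls. With simulated clones that differ by a dispersion of 0.00857, clone sums (15529 genes) recovered 47.8%, 86.6% and 97.0% with 15 false calls, the library-level contrast (15342 genes) gave 3522 false calls, the genes shared by all 4 clone pairs held 318 false calls, and voom with a clone correlation gave 134. In a simulated list test the changed list passed with camera (adjusted p = 1.04e-35, and 0.0298 with an estimated correlation) and with fry (adjusted p = 9.54e-05). In it 0 of 34 unchanged lists were called. The simulation did not test lists whose genes vary together. It therefore cannot show whether the preset correlation of 0.01 holds for the real lists.

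Alternatives were RLE size factors, no or a stricter low-count filter, DESeq2 1.42.0, voom with clone as a random block (consensus correlation 0.257), each library or clone left out, the replicate number as a block, subsets of the libraries, camera with an estimated correlation, fry, and a 2-fold minimum. Leaving out the abundant unnamed ID, blocking the screen's list tests by replicate number and repeating the chromosome check with other settings were chosen after seeing the data.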

Results

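Messenger RNA was sequenced from E14 cells, a mouse embryonic stem cell line, at stages of neural differentiation. The cells were grown on gelatin in 2i/LIF medium, in which inhibitors of MEK and GSK3 and the cytokine LIF hold them in an undifferentiated state, and were then moved to NDiff medium, a serum-free medium that permits neural differentiation. A first set of 6 libraries came from the pool of cells of a CRISPR knockout screen, in which each cell carries a guide RNA against some gene, with 2 libraries on each of days 0, 4 and 10. A second set of 12 libraries came from day 4 of differentiation of 2 wild-type clones and 2 clones mutated in Peds1, with 3 libraries per clone. Peds1, also known by the older symbol Tmem189, encodes plasmanylethanolamine desaturase, the enzyme that forms the vinyl ether bond of plasmalogens. Total counts per library, in M (mega) counts, were 16.23 and 16.24 M on day 0, 16.44 and 16.27 M on day 4, and 17.84 and 18.07 M on day 10. In the clones they were 15.72, 19.21 and 17.28 M for wild-type clone 1, and 14.86, 21.66 and 15.17 M for wild-type clone 2. They were 14.79, 16.79 and 20.86 M for knockout clone 1, and 16.81, 18.51 and 18.2 M for knockout clone 2. Expression levels are given in CPM (counts per M of the TMM-scaled library size) as mean ± SD, and fold changes on the log2 scale ± SE.

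The comparison of day 4 with day 0 of the screen pool asked what changed as the cells left the undifferentiated state. Genes of naive pluripotency fell and genes of the formative state rose. Tfcp2l1, a transcription factor of the naive state, fell from 1440 ± 29.4 CPM to 44.2 ± 7.02 CPM (SD, n = 2), a log2 change of −5.02 ± 0.09 (edgeR, adjusted p = 1.26e-19). Fgf4, which encodes a fibroblast growth factor made by stem cells, fell from 433 ± 11.1 to 58.0 ± 4.68 CPM (SD, n = 2). Dnmt3b, a de novo DNA methyltransferase, rose from 125 ± 2.49 to 915 ± 7.10 CPM (SD, n = 2), a log2 change of 2.87 ± 0.06 (edgeR, adjusted p = 2.65e-19). Pax6, a transcription factor of neural progenitors, rose from 0.437 ± 0.0401 to 44.1 ± 1.99 CPM (SD, n = 2).

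All 15 naive pluripotency genes fell by day 4, with a median log2 change of −2.90 (camera, adjusted p = 4.09e-07; adjusted p = 0.406 with an estimated correlation). Tcl1, an activator of AKT signaling, changed by −4.65 and Tbx3 by −3.24. All 10 formative and primed genes rose, with a median of 2.74 (camera, adjusted p = 4.92e-05; adjusted p = 0.3 with an estimated correlation). Among them were Dnmt3a at 2.17 and Lef1, a transcription factor of the Wnt pathway, at 4.51. The Wnt ligand gene Wnt8a stood at 37.2 ± 1.22 CPM (SD, n = 2) on day 4 against 2 counts on day 0, a ratio of 553 with a counting interval of 153 to 4570. Of 18 neural progenitor genes 12 rose and 4 fell, with a median of 2.23, or 2.12 with genes absent on day 0 set to their bound (camera, adjusted p = 0.00781; adjusted p = 0.406 with an estimated correlation). Sox3 rose by 5.14, the glutamate transporter gene Slc1a3 by 3.39 and Prom1 by 2.86. Of 17 neurogenic commitment genes 10 rose and 0 fell, with a median of 1.18 (camera, adjusted p = 0.00781; adjusted p = 0.406 with an estimated correlation). The Notch ligand gene Dll1 rose from 0.369 ± 0.136 to 31.0 ± 0.345 CPM (SD, n = 2). Of 15 midbrain and hindbrain genes 10 rose, 9 when adjusted over the list alone, with a median of 3.03, or 2.75 with the bounds (camera, adjusted p = 0.0014; adjusted p = 0.406 with an estimated correlation). Hoxb1 had 0 counts on day 0 and was at least 279-fold higher on day 4, and Gbx2 rose by 4.04. Counts adjusted over the list alone equalled those over all genes for the other 4 of these lists.

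Signaling and metabolic genes moved as well. The medium changed along with the day, from 2i/LIF with its MEK inhibitor to NDiff. Effects of the medium and of differentiation therefore cannot be told apart here. Of 12 FGF and ERK target genes 9 rose and 3 fell, with a median of 1.90 (camera, adjusted p = 0.0239; adjusted p = 0.406 with an estimated correlation). The ERK phosphatase gene Dusp4 rose by 4.94, the feedback inhibitor gene Spry4 by 5.32 and Myc by 4.16. Of 18 glycolysis and hypoxia genes 16 fell and 2 rose, with a median of −1.09 (camera, adjusted p = 0.000168; adjusted p = 0.472 with an estimated correlation). Hexokinase 2, Hk2, fell from 926 ± 0.843 to 149 ± 6.50 CPM and the lactate dehydrogenase gene Ldha from 2320 ± 82.3 to 929 ± 12.3 CPM (SD, n = 2). Of 24 cholesterol synthesis and uptake genes 17 rose and 0 fell, with a median of 0.34 (camera, adjusted p = 0.00781; adjusted p = 0.472 with an estimated correlation). The lanosterol synthase gene Lss rose by 1.27. The counts adjusted over the list alone were the same for these 3 lists. Of 20 postmitotic neuron genes 14 rose and 6 fell, over all genes and adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0511, and 0.0365 without day 0 replicate 1). Crmp1 rose by 3.83 while Stmn2 changed by −2.28 and Mapt, which encodes tau, by −3.72.

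The largest rises by day 4 belonged to genes with few or no counts on day 0. Wt1, a zinc finger transcription factor, was at least 287-fold higher, Ccdc194 at least 222-fold and Fat3 at least 120-fold, each against 0 counts on day 0. The ratio was 1540 for the carbonic anhydrase gene Car4 (counting interval 276 to 60900), 367 for Olig3 (101 to 3030) and 336 for Ndnf (59.9 to 13300). Cubn, which encodes the endocytic receptor cubilin, rose from 0.269 ± 0.00459 to 324 ± 44.0 CPM (SD, n = 2). The largest falls included Ly6a, which encodes the surface antigen Sca-1, from 110 ± 3.98 to 0.0588 ± 0.0831 CPM (SD, n = 2), a ratio of 1860 (514 to 15300). The log2 change was −8.12 for the channel gene Trpm1, −7.55 for the choline breakdown gene Dmgdh and −6.91 for Serpinb1a. It was −6.66 for the aquaporin gene Aqp3 and −6.64 for Pramef17. The ratio was 199 for Aspa (54.7 to 1650), 172 for Bhmt (58.5 to 838), 143 for Aox3 (48.5 to 696) and 116 for Sash3 (39.4 to 567), all lower on day 4. Among all genes tested 5544 rose and 5442 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 4949 of these differed at least 2-fold. The 2 libraries of a day came from the same pool, so the test speaks for this pool and its cultures.

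**Figure D1:**
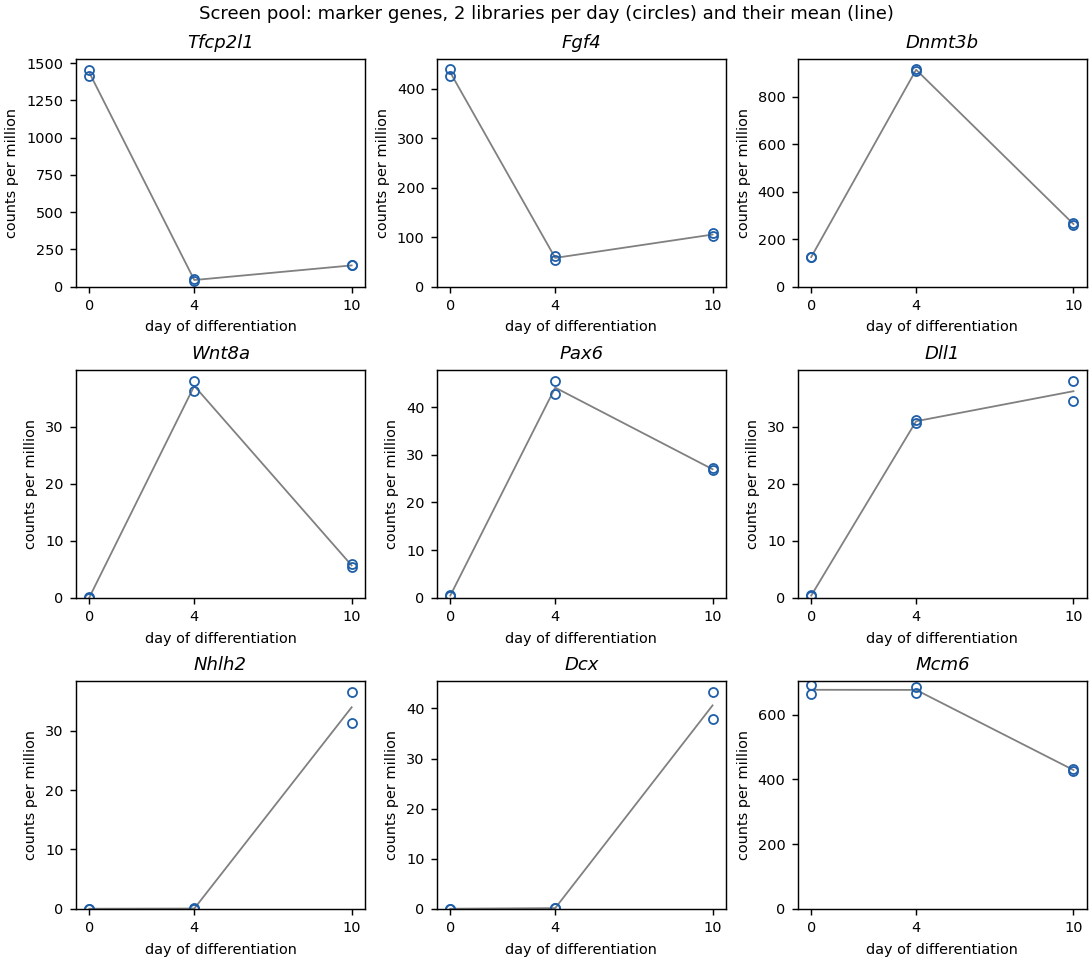
Expression of 9 genes in the screen pool in CPM against the day of differentiation, with each circle 1 library (2 per day) and the line through the means. Tfcp2l1 fell from 1440 CPM on day 0 to 44.2 CPM on day 4, Dnmt3b peaked at 915 CPM on day 4, and Dcx reached 40.6 CPM on day 10.

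The comparison of day 10 with day 4 asked what followed as neurons formed. Genes of neurogenesis and of neurons rose, genes of the formative state and of DNA replication fell, and genes of non-neural lineages rose too. Dcx, which encodes the microtubule protein doublecortin of young neurons, rose from 0.118 ± 0.000754 to 40.6 ± 3.78 CPM (SD, n = 2), a log2 change of 8.34 ± 0.25 (edgeR, adjusted p = 1.65e-16). Fabp7, a fatty acid binding protein of radial glia, rose from 0.207 ± 0.127 to 72.8 ± 1.05 CPM (SD, n = 2). Acta2, which encodes smooth muscle actin, rose from 0.531 ± 0.00339 to 118 ± 5.95 CPM (SD, n = 2), a log2 change of 7.78 ± 0.16 (edgeR, adjusted p = 2.83e-19).

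Of 17 neurogenic commitment genes 16 rose between days 4 and 10, with a median log2 change of 2.44 (camera, adjusted p = 4.73e-06; adjusted p = 0.199 with an estimated correlation). Nhlh1 rose by 6.72, while Nhlh2, at 34 ± 3.63 CPM (SD, n = 2), had a ratio of 1150 over its 1 count on day 4 (counting interval 207 to 45600) and Neurod4 a ratio of 143 (48.5 to 694). Of 20 postmitotic neuron genes 17 rose and 2 fell, with a median of 1.62 (camera, adjusted p = 1.81e-05; adjusted p = 0.199 with an estimated correlation). The neurofilament gene Nefm rose by 3.03, the microtubule protein gene Map2 by 2.39 and the RNA-binding protein gene Elavl4 by 2.48. Of 17 synapse and transmission genes 13 rose and 1 fell, with a median of 1.38 (camera, adjusted p = 0.00146; adjusted p = 0.199 with an estimated correlation). Slc17a6, a vesicular glutamate transporter, had 0 counts on day 4 and was at least 44.7-fold higher at 3.97 ± 0.437 CPM (SD, n = 2), while the synapsin gene Syn1 fell by 0.92. The counts adjusted over the list alone were the same for these 3 lists. Of 18 neural progenitor genes 11 rose and 4 fell, over all genes and adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0756, and 0.0476 without day 4 replicate 1). Sox9 rose by 4.19 and Zic1 by 3.65 in it.

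Of 13 neural crest and mesenchyme genes 11 rose and 1 fell, with a median of 3.83 (camera, adjusted p = 6.2e-05; adjusted p = 0.199 with an estimated correlation). The collagen gene Col1a1 rose from 4.54 ± 0.221 to 102 ± 4.14 CPM (SD, n = 2), and the neural crest transcription factor genes Tfap2b and Pax3 rose by 6.70 and 5.43. Of 10 mesoderm and endoderm genes 7 rose, 8 when adjusted over the list alone, with a median of 1.69 (camera, adjusted p = 0.00488; adjusted p = 0.199 with an estimated correlation). Gata4 rose from 21.5 ± 0.155 to 157 ± 9.86 CPM and Sox17 from 10.2 ± 0.978 to 73.9 ± 3.70 CPM (SD, n = 2), and Foxa2 rose by 2.53. Of 9 BMP target genes 7 rose, with a median of 2.45 (camera, adjusted p = 0.00392; adjusted p = 0.436 with an estimated correlation). Id2 rose by 2.52, Id3 by 2.53 and Id4 by 3.26. Of 15 naive pluripotency genes 13 rose and 1 fell, with a median of 0.76 (camera, adjusted p = 0.00206; adjusted p = 0.442 with an estimated correlation). Tfcp2l1 rose from 44.2 ± 7.02 to 142 ± 0.647 CPM (SD, n = 2), still below its 1440 ± 29.4 CPM on day 0. Of 8 Notch target genes 6 rose, with a median of 0.65 (camera, adjusted p = 0.0383, and 0.08 without day 4 replicate 1; adjusted p = 0.483 with an estimated correlation), including Hey1 at 2.54. Except for the mesoderm and endoderm list, the counts adjusted over the list alone were the same.

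Of 25 DNA replication genes 22 fell from day 4 to day 10 and 0 rose, with a median of −0.44 (camera, adjusted p = 3.08e-07; adjusted p = 0.199 with an estimated correlation). The helicase genes Hells and Mcm6 changed by −0.89 and −0.66, and the exonuclease gene Exo1 by −0.80. Of 29 mitosis genes 14 fell and 1 rose, with a median of −0.16 (camera, adjusted p = 0.00392; adjusted p = 0.199 with an estimated correlation), and the cyclin gene Ccnb1 fell by 0.47. Of 10 cell cycle exit genes 8 rose, with a median of 0.78 (camera, adjusted p = 0.00739; adjusted p = 0.442 with an estimated correlation), among them the antiproliferative genes Btg1 at 1.44 and Btg2 at 1.41. Of 10 formative and primed genes 8 fell and 1 rose, 2 when adjusted over the list alone, with a median of −0.82 (camera, adjusted p = 0.00267; adjusted p = 0.199 with an estimated correlation), and Dnmt3b fell from 915 ± 7.10 to 264 ± 4.66 CPM (SD, n = 2). Of 19 p53 target genes 14 rose and 1 fell, with a median of 0.30 (camera, adjusted p = 0.00772; adjusted p = 0.442 with an estimated correlation), among them Plk2 at 1.67 and the cell cycle inhibitor gene Cdkn1a at 1.14. Of 18 glycolysis and hypoxia genes 12 rose and 3 fell, with a median of 0.40 (camera, adjusted p = 0.0298; adjusted p = 0.565 with an estimated correlation), a call lost without day 4 replicate 1 (adjusted p = 0.095) or day 10 replicate 1 (adjusted p = 0.0537). Except for the formative list, the counts adjusted over the list alone were the same.

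Among single genes, the extracellular matrix gene Tnc rose by 8.17, Pou3f3 by 7.64, Fat4 by 7.52 and the transthyretin gene Ttr by 7.08 from day 4 to day 10, and the collagen gene Col3a1 had a ratio of 247 (counting interval 68 to 2040). Genes that had risen by day 4 were among those that fell furthest afterwards. Hoxb1 fell from 28.2 ± 4.52 to 1.74 ± 0.135 CPM, Olig3 from 24.7 ± 5.33 to 2.19 ± 0.26 CPM and Wt1 from 28.9 ± 1.28 to 3.41 ± 0.455 CPM (SD, n = 2). The log2 change was −5.72 for the mesodermal gene Meox1, −2.97 for the fatty acid transport gene Slc27a2 and −2.90 for both Cyp2b23 and Nckap1l. It was −2.71 for Wnt8a, −2.58 for the kinase gene Pim2 and −2.52 for the actinin gene Actn3. Among all genes tested 4625 rose and 4182 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 2556 of these differed at least 2-fold, 1967 of them higher and 589 lower on day 10. Between day 0 and day 10, 5531 genes rose and 5594 fell, 4959 of them at least 2-fold.

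**Figure D2:**
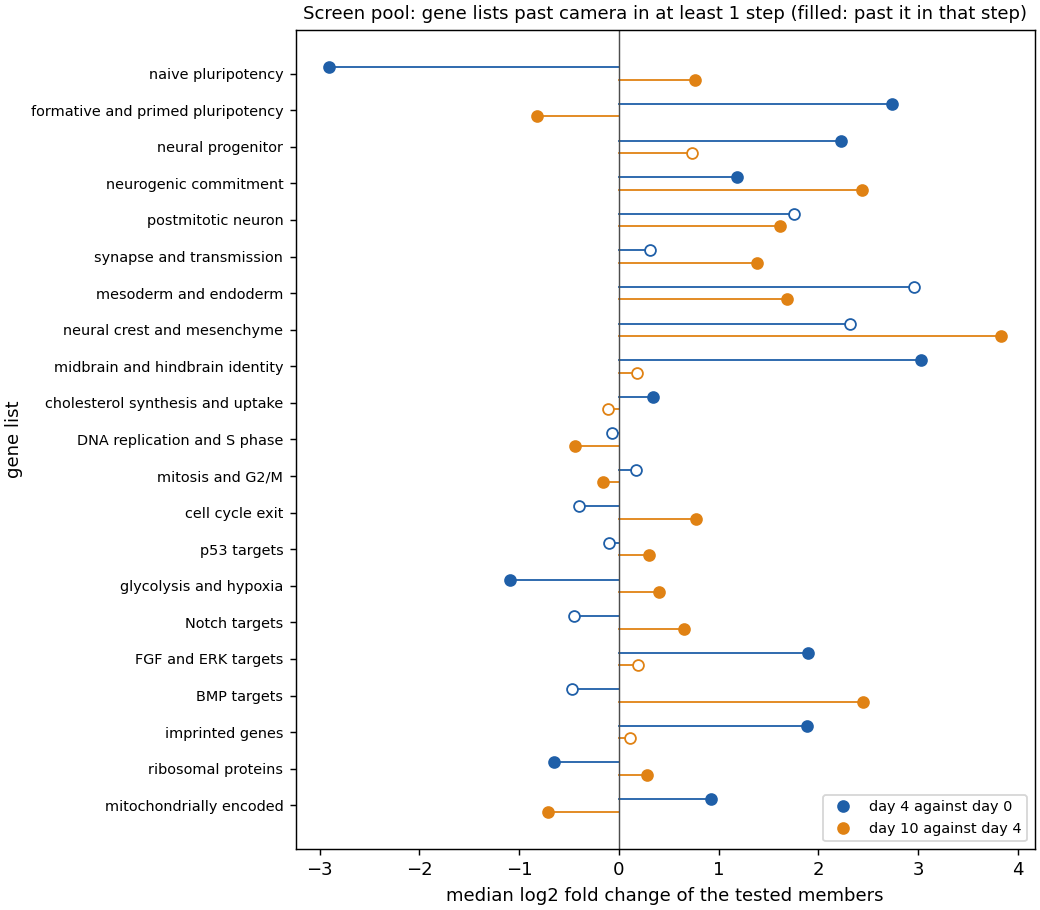
Median log2 fold change of the tested members of 21 gene lists in the screen pool, day 4 against day 0 in blue and day 10 against day 4 in orange, with filled points where camera passed in that step. Naive pluripotency genes had medians of −2.90 and 0.76 in the first and the later step, and neural crest and mesenchyme genes had the largest later median at 3.83.

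The clone comparison asked how the Peds1 knockout clones differed from the wild-type clones at day 4. Peds1 transcript levels were lower in the libraries labelled as knockout. They were 40.2 ± 1.36 CPM in wild-type clone 1 and 41.0 ± 0.624 CPM in wild-type clone 2, against 18.2 ± 2.56 CPM in knockout clone 1 and 24.4 ± 0.551 CPM in knockout clone 2 (SD, n = 3). Values in single libraries ran from 39.1 to 41.7 CPM in the wild-type clones and from 15.5 to 25.0 CPM in the knockout clones, so all 12 libraries fell on the side of their label. In the screen pool Peds1 stood at 29.5 ± 2.55, 32.9 ± 3.25 and 33.0 ± 1.06 CPM on days 0, 4 and 10 (SD, n = 2), with no change detected in either step (edgeR, adjusted p = 0.159 and 0.991). With libraries as replicates the log2 change was −0.95 ± 0.05 (edgeR, adjusted p = 2.34e-12), and with clones as replicates −0.94 (edgeR, adjusted p = 0.143). That clone-level p was 0.0377 without knockout clone 1 replicate 3. Gene counts do not show the edit itself, and a frameshift need not lower the RNA.

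Of the 15 genes called between genotypes 5 were contractile or actin-associated, and all 5 were lower in the knockout clones. This grouping was chosen after the calls were seen and was not tested as a list here. Acta1, which encodes skeletal muscle actin, stood at 8.79 ± 1.63 and 9.86 ± 1.75 CPM in the wild-type clones and at 3.05 ± 0.331 and 2.62 ± 0.267 CPM in the knockout clones (SD, n = 3), a log2 change of −1.73 ± 0.15 with clones as replicates (edgeR, adjusted p = 0.0153). The cardiac actin gene Actc1 changed by −1.43 (edgeR, adjusted p = 0.0278) and the myosin light chain gene Myl9 by −0.88 (adjusted p = 0.0153). The calponin gene Cnn2 changed by −0.58 (edgeR, adjusted p = 0.0371) and Vcl, which encodes the adhesion protein vinculin, by −0.52 (adjusted p = 0.0278). Nes, which encodes the neural progenitor filament nestin, fell from 182 ± 2.49 and 180 ± 7.27 CPM to 116 ± 3.88 and 121 ± 6.13 CPM (SD, n = 3; edgeR, adjusted p = 0.0168). Higher in the knockout clones was Halr1, a long noncoding RNA gene near the Hoxa cluster, at 1.24 ± 0.09 (edgeR, adjusted p = 0.00616). Also higher were the junction protein gene Jam2 at 1.28 (adjusted p = 0.0294), the germ cell gene Tex19.1 at 1.02 (adjusted p = 0.0153). The pluripotency gene Dppa5a stood at 0.56 (edgeR, adjusted p = 0.0278) and Insig1, a regulator of sterol synthesis, at 0.54 (adjusted p = 0.0278). With clones as replicates 6 genes rose and 9 fell of 17914 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1297 had an unadjusted p under 0.05. Grouping wild-type clone 1 with knockout clone 2 against the other 2 clones gave 11 genes by the same test and 1232 at an unadjusted p under 0.05. Grouping wild-type clone 1 with knockout clone 1 gave 0 and 335, so the genotype split gave the most genes of the 3 but barely more than 1 of the others. DESeq2 called 116 genes, and voom with clone as a random block called 276. A stricter low-count filter left 6 genes, and Jam2, Dppa5a, Insig1, Actc1, Cnn2 and Vcl did not pass there (edgeR, adjusted p between 0.0556 and 0.0815). Without wild-type clone 1 replicate 1, 5 genes passed, and the calls of Jam2, Tex19.1, Dppa5a, Insig1, Actc1, Cnn2 and Vcl ended at adjusted p between 0.0526 and 0.0823. The calls of Jam2 without wild-type clone 2 replicate 1, and of Insig1 and Cnn2 without wild-type clone 2 replicate 3, ended too, at adjusted p = 0.0502, 0.0508 and 0.0768. The other 4 called genes fell outside the rule for named genes and were chosen after their values were seen. C78283 stood at 1.57 and 1700013H16Rik at −3.64, with edgeR adjusted p of 0.12 and 0.0149 without wild-type clone 1 replicate 1. Of the X-linked pair Xlr5a had a ratio of 75.7 (counting interval 13.2 to 3030) and Xlr5c a ratio of 37.3 (9.97 to 314), both lower in the knockout clones, and their calls ended without that library (edgeR, adjusted p = 0.058 and 0.0572).

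**Figure D3:**
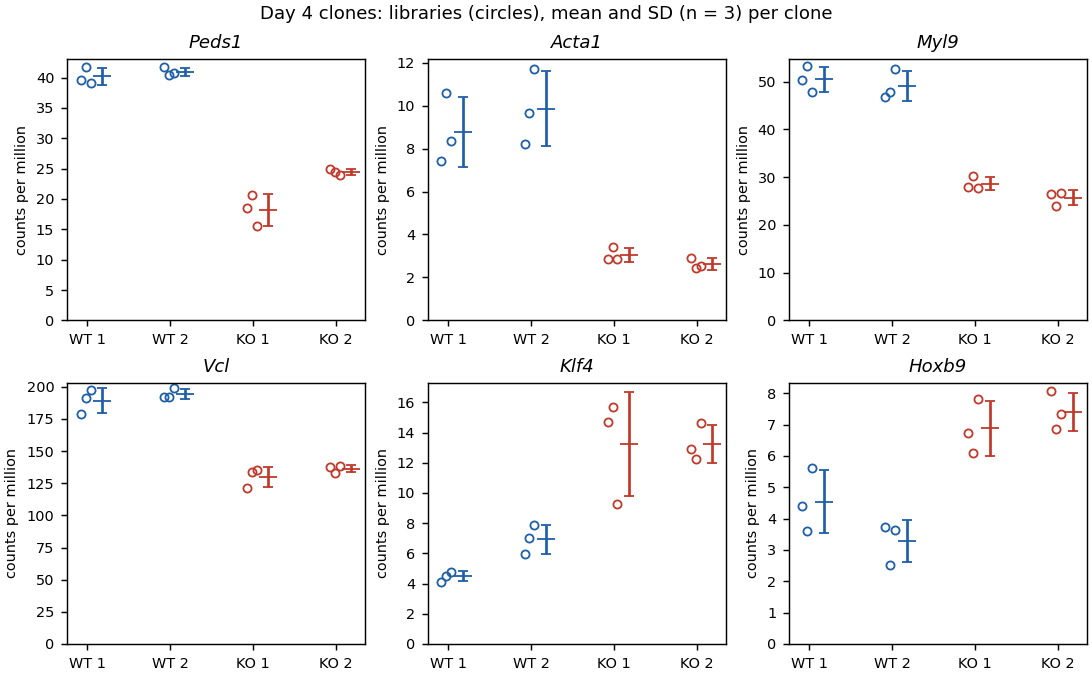
Expression of 6 genes at day 4 in CPM for 2 wild-type clones (WT) and 2 Peds1 knockout clones (KO), with each circle 1 library (3 per clone) and bars for the mean and SD. Acta1 stood at 8.79 and 9.86 CPM in the wild-type clones against 3.05 and 2.62 CPM in the knockout clones, and Klf4 at 4.49 and 6.94 CPM against 13.2 and 13.3 CPM.

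Taking each knockout clone against each wild-type clone, 210 genes differed the same way in all 4 pairs, 78 higher and 132 lower in the knockout clones. The same rule gave 318 false calls on simulated clones that differ, more than the 210 found, so that simulation sets no expected count here. It shows only that the rule also calls unchanged genes where clones differ, so these genes describe the clones at hand. Trap1a rose from 19.9 ± 0.0636 and 12.9 ± 1.57 CPM to 45.7 ± 4.73 and 42.3 ± 2.31 CPM (SD, n = 3), a log2 change of 1.46 ± 0.06 with libraries as replicates (edgeR, adjusted p = 1.92e-15). The naive pluripotency gene Klf4 rose by 1.24, Hoxb9 by 0.90, Porcn, whose product modifies Wnt ligands, by 0.88 and Zfp936 by 0.80. The homeobox gene Rhox5 on the X chromosome fell from 10.7 ± 0.534 and 33.9 ± 1.11 CPM to 1.31 ± 0.157 and 4.08 ± 0.139 CPM (SD, n = 3), and the X-linked genes Xlr3a and Xlr3b changed by −2.07 and −1.75. Reads of near-identical Xlr copies can be split between genes, so single members are uncertain. With libraries as replicates 1053 genes rose and 1283 fell, and 90 of them differed at least 2-fold. Grouping wild-type clone 1 with knockout clone 2 gave 2306 genes by the same test and 112 in all 4 pairs, and grouping it with knockout clone 1 gave 324 and 19. The library counts therefore describe these 4 clones, and how much of them belongs to the genotype stays open.

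Among the gene lists, those of naive pluripotency and posterior Hox genes passed as higher in the knockout clones. That of immediate early and heat shock genes passed as lower. With clones as replicates they passed camera with the preset correlation, but not with an estimated one and not fry (adjusted p = 0.636 for each). With libraries as replicates, which speak for these 4 clones only, they passed camera with the preset correlation (adjusted p = 1.2e-05, 7.06e-07 and 5.94e-05). They passed fry there too (adjusted p = 0.00625, 0.00127 and 0.00127), but not camera with an estimated correlation. The 15 naive genes had a median log2 change of 0.54 (camera, adjusted p = 7.68e-05; adjusted p = 0.847 with an estimated correlation), with 11 higher and 4 lower. Of these 0 passed edgeR over all genes, with 8 higher when adjusted over the list alone, 8 at an unadjusted p under 0.05, 5 called by DESeq2 and 3 by voom. Klf2 stood at 0.54 (edgeR, adjusted p = 0.0999), Klf4 at 1.19 (adjusted p = 0.159) and Zfp42 at 0.54 (adjusted p = 0.159). The 15 posterior Hox genes had a median of 0.58 (camera, adjusted p = 5.78e-06; adjusted p = 0.847 with an estimated correlation), and 15 of 15 were higher. Of these 15 Hox genes 0 passed edgeR over all genes, with 4 when adjusted over the list alone, 8 at an unadjusted p under 0.05, and 1 each by DESeq2 and voom. Hoxb9 stood at 0.89 (edgeR, adjusted p = 0.263) and Hoxa4 at 0.58 (adjusted p = 0.397). The 12 immediate early and heat shock genes had a median of −0.25 (camera, adjusted p = 0.000332; adjusted p = 0.847 with an estimated correlation), and 12 of 12 were lower. Of these 12 genes 0 passed edgeR over all genes, with 3 when adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 by DESeq2 and 3 by voom. Junb stood at −0.71 (edgeR, adjusted p = 0.218) and Hspa1b at −0.49 (adjusted p = 0.3). Wild-type clone 2 also differed from clone 1 in this list, by a median of 0.16 (camera, adjusted p = 0.0455; adjusted p = 0.562 with an estimated correlation). Between the knockout clones the median was 0.008 (camera, adjusted p = 0.603). The naive list did not pass without wild-type clone 1 (camera, adjusted p = 0.14).

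Genes of the pathway in which Peds1 acts showed no detected change. Of 14 ether lipid and plasmalogen genes 0 passed edgeR over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and 0 were called by DESeq2 or voom, with a median log2 change of 0.06 (camera, adjusted p = 0.445). Gnpat, the first enzyme of ether lipid synthesis, stood at 152 ± 4.67 CPM in wild-type and 142 ± 5.89 CPM in knockout libraries. Here the SD is over n = 6 libraries from 2 clones of each genotype, so it is not a spread between clones. Of 26 peroxisome genes 0 passed edgeR over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, and 0 were called by DESeq2 or voom, with a median of −0.03 (camera, adjusted p = 0.448). On simulated data at this size, with clones that differ, 47.8% of genes changed 1.5-fold and 86.6% of those changed 2-fold were recovered. The simulation changed 200 genes and gave all genes the same between-clone dispersion, while the real test called 15 genes. In the real test Peds1 itself, at −0.94, did not pass (edgeR, adjusted p = 0.143). Recovery in the real comparison may therefore be lower than in the simulation.

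The clone difference was also placed along the time course of the screen. Pool and clones differed at the same day 4. Ddx3y, Eif2s3y and Uty had counts in the screen but 0 in the clones. Mitochondrially encoded genes held 4.84% and 5.17% of the counts on day 4 of the screen, against 0.599% to 0.861% in the clones. The time course of the pool may therefore not carry over to the clones. Of the 200 genes that rose furthest from day 4 to day 10, 191 were tested, and they were lower in the knockout clones as a list, with a median log2 change of −0.11 (camera, adjusted p = 0.00348; adjusted p = 0.614 with an estimated correlation). The 200 that fell furthest over those days, all tested, were higher as a list, with a median of 0.06 (camera, adjusted p = 0.0305; adjusted p = 0.56 with an estimated correlation). The genes that rose or fell furthest by day 4 (200 and 174 tested) had medians of −0.03 and 0.02 (camera, adjusted p = 0.223 and 0.238). Without wild-type clone 2 or without knockout clone 1, 0 of these 4 lists passed camera, and without wild-type clone 1 a single list did.

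The 2 clones of 1 genotype also differed. Rhox5 was higher in wild-type clone 2 than in wild-type clone 1, by 1.66 (edgeR, adjusted p = 5.69e-13), and so were the endoderm gene Gata6 by 1.77 (adjusted p = 1.59e-06), Cubn by 1.89 (adjusted p = 0.000267) and the Nodal co-receptor gene Tdgf1 by 1.61 (adjusted p = 0.00563). Efhc2 was lower, a change of −2.13 from 38.4 ± 3.60 to 8.66 ± 1.01 CPM (SD, n = 3), and the meiosis gene Stra8 changed by −1.60 and Klhl13 by −0.95. Of 12 FGF and ERK target genes 11 were higher in wild-type clone 2, all 12 when adjusted over the list alone, with a median of 0.58 (camera, adjusted p = 9.74e-10; adjusted p = 0.052 with an estimated correlation), among them Spry2 at 0.48 and Dusp6 at 0.55. Of 14 naive pluripotency genes 6 were higher, 7 when adjusted over the list alone, with a median of 0.57 (camera, adjusted p = 4.11e-05; adjusted p = 0.562 with an estimated correlation), among them Klf5 at 0.64 and Fgf4 at 1.27. With 10 of 34 lists past camera, 1130 genes were higher and 849 lower in wild-type clone 2 (edgeR quasi-likelihood test, adjusted p under 0.05), 217 of them at least 2-fold. The count was 861 without wild-type clone 1 replicate 2, 1267 without its replicate 3, 856 without wild-type clone 2 replicate 1 and 732 without its replicate 2. Snhg14 at 2.01, Efnb1 at −0.93 and Plxna2 at −0.89 passed with all libraries but not without wild-type clone 2 replicate 2 (adjusted p = 0.133, 0.116 and 0.0767).

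Between the knockout clones, the midbrain and hindbrain list and the imprinted list were higher in clone 2 by camera with the preset correlation. They also passed fry (adjusted p = 0.00652 and 0.00452), but not camera with an estimated correlation. Cubn was higher by 2.01 (edgeR, adjusted p = 0.000944) and the laminin gene Lama1 by 1.56 (adjusted p = 0.00532), while Efhc2 changed by −4.86, from 37.7 ± 3.78 to 1.31 ± 0.317 CPM (SD, n = 3), and Xlr3a by −2.55. Of 13 midbrain and hindbrain genes 8 were higher, 12 when adjusted over the list alone, with a median of 0.70 (camera, adjusted p = 1.61e-10; adjusted p = 0.146 with an estimated correlation), among them Hoxb2 at 0.82 and Hoxa2 at 0.64. Of 23 imprinted genes 7 were higher and 1 lower, 10 and 1 when adjusted over the list alone, with a median of 0.31 (camera, adjusted p = 3.07e-06; adjusted p = 0.146 with an estimated correlation), among them Mest, which rose from 240 ± 34.1 to 559 ± 33.6 CPM (SD, n = 3), and Dlk1 at 0.76. With 15 of 34 lists past camera, 358 genes were higher and 330 lower in knockout clone 2 (edgeR quasi-likelihood test, adjusted p under 0.05), 68 of them at least 2-fold. The count was 289 without knockout clone 1 replicate 1, 337 without its replicate 2, 309 without knockout clone 2 replicate 1 and 403 without its replicate 3. Crabp1 at 1.67, Tmem132c at 1.47, Enpp2 at −1.31, Otx2 at −1.20 and Adgra2 at −0.88 passed with all libraries but not without knockout clone 2 replicate 1 (adjusted p = 0.12, 0.102, 0.0767, 0.0733 and 0.0605).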

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

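The predictions on the general actin list, the mesenchyme markers and the summed Xlr counts were written before their values were seen, and the other tests in this part were chosen after the results were seen. The 2 knockout clones differed in 688 genes (edgeR, tested directly as clone 2 against clone 1), and 10 splits of the 6 libraries are too few for a share under 0.05, with 688 genes for the real split (value 1) and 1 for the highest other. The count was 289 without knockout clone 1 replicate 1, 337 without its replicate 2, 309 without knockout clone 2 replicate 1 and 403 without its replicate 3. Peds1 itself was higher in clone 2 by 0.43 (edgeR, adjusted p = 0.00233). Rhox5 was higher by 1.62, Xlr3a changed by −2.55 and Xlr3b by −1.62 (edgeR, adjusted p = 7.23e-07, 1.52e-13 and 6.01e-06). The naive pluripotency list had a median difference of −0.26 (camera, adjusted p = 0.022; 0.474 with an estimated correlation) and the posterior Hox list of 0.41 (camera, adjusted p = 8.89e-06; 0.146 with an estimated correlation).

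For the comparison of genotypes with libraries as replicates, 1 of 100 splits of the 12 libraries, the real one, gave 2336 genes. The highest other gave 597. The other splits drawn broke up the clones, so this test cannot tell a genotype difference from differences between clones. The crossed split by whole clones, wild-type clone 1 and knockout clone 2 against the others, was not among those drawn and gave 2306 genes, and wild-type clone 1 and knockout clone 1 against the others gave 324. Differences between clones are therefore part of the structure of the samples. For wild-type clone 2 against clone 1, 10 splits are too few for a share under 0.05, with 1979 genes for the real split (value 1) and 1 for the highest other. That count was 861 without wild-type clone 1 replicate 2, 1267 without its replicate 3, 856 without wild-type clone 2 replicate 1 and 732 without its replicate 2.

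The actin-associated genes Acta1, Actc1, Myl9, Cnn2 and Vcl were lower in the knockout clones. Without wild-type clone 1 replicate 1, the wild-type library that differed most from its replicates, the median of the 5 was −0.88, as with all libraries, which argues against that library as the source of the fall, although Actc1, Cnn2 and Vcl then had adjusted p of 0.0526, 0.0823 and 0.0526 (edgeR). The pattern may be part of a lower level of actin and SRF target genes in general. The other 36 tested genes of that kind had a median of −0.16 with 32 lower (camera, p = 7.27e-07, and p = 0.0955 with an estimated correlation). That list was written after the 5 genes were called and was tested in the same clones, so it is no independent support. How far it differed between clones of 1 genotype was not tested. Fewer mesenchymal cells cannot be told apart from such a general fall by the prediction made for it. The 26 mesenchyme markers had a median of −0.0143, with 13 lower and an SD of 0.56. That SD is wider than the smallest fall of the 5 genes, −0.52 in Vcl, though not wider than their median fall of −0.88. Sparc at 164 CPM changed by −0.18 and Fstl1 at 150 CPM by 0.04.

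As lists, naive pluripotency and posterior Hox genes had median changes of 0.54 and 0.58 in the knockout clones (camera, adjusted p = 7.68e-05 and 5.78e-06; adjusted p = 0.847 for both with an estimated correlation). Of the 15 genes of each list 0 passed edgeR over all genes, with 8 of each at an unadjusted p under 0.05, 5 and 1 called by DESeq2 and 3 and 1 by voom. Of the 200 genes that fell furthest by day 4, the 174 tested had a median of 0.02 with an SD of 0.46 (camera, adjusted p = 0.238), below the naive median by more than that SD, which argues against undifferentiated cells left over in the knockout cultures as the whole cause. For the naive genes, differences between clones without the mutation may account for it, since the 2 wild-type clones differed by 0.57. For the posterior Hox genes this cannot be told apart, because the wild-type clones differed by −0.15 and the knockout clones by 0.41, and an effect of the mutation stays open for both lists.

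Xlr genes and Rhox5 were lower in the knockout clones. The summed CPM of 10 Xlr genes was 43.5 ± 3.38 and 53.5 ± 1.25 in the wild-type clones against 23.1 ± 1.68 and 4.92 ± 0.361 in the knockout clones (SD, n = 3), a log2 ratio of −1.79, which argues against reads moving between near-identical copies. The median of 611 tested X-linked genes was 0.0368 with an SD of 0.53, which argues against a lower dosage of the X chromosome. Differences between clones without the mutation cannot be told apart from an effect of the mutation, because the 5 genes differed by a median of 0.26 between the wild-type clones but 1.62 between the knockout clones, against −3.04 between genotypes.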

How the results depend on the processing

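The alternative without the abundant unnamed ID, the replicate block of the screen's list tests and the chromosome settings were chosen after seeing the data. Under any alternative run 0 named genes reversed, and 0 lists passed in both directions. A list could still pass newly against its main direction. For day 4 against day 0 the synapse and transmission list passed fry as lower (adjusted p = 0.000563), while camera put it higher without a call (adjusted p = 0.868). With at least 2-fold required, 4949 (day 4 against 0), 2556 (day 10 against 4), 4959 (day 10 against 0), 9 (clones as replicates), 90 (libraries as replicates), 217 (wild-type clones) and 68 (knockout clones) genes passed, fewer by construction. With clones as replicates 15 genes passed, but 395 with no low-count filter, 6 with a stricter one, 116 with DESeq2, 276 with voom and clone as a random block, 181 with the replicate block added, and 5 to 22 with 1 library left out (5 without wild-type clone 1 replicate 1). With 1 clone left out 31 to 218 passed, namely 194 without wild-type clone 1, 218 without wild-type clone 2, 31 without knockout clone 1 and 57 without knockout clone 2, with the lone clone assumed to vary like the pair. With libraries as replicates 1688 to 2377 genes passed with 1 library left out, and 1033 in 2 groups of 6. Between the wild-type clones 732 to 2310 passed with 1 library left out (861, 1267, 856 and 732 without wild-type clone 1 replicate 2 or 3 or clone 2 replicate 1 or 2) and between the knockout clones 289 to 960 (289, 337, 309 and 403 without knockout clone 1 replicate 1 or 2 or clone 2 replicate 1 or 3). Peds1 itself, −0.94 with adjusted p = 0.143 at clone level, passed with no filter (−0.95, adjusted p = 8.83e-20), DESeq2 (−0.94, 1.88e-07), voom (−0.96, 9.16e-06), voom with the replicate block (−0.95, 3.2e-05), without knockout clone 1 replicate 3 (−0.88, 0.0377), without knockout clone 1 (−0.74, 0.0182) and without knockout clone 2 (−1.18, 2.16e-05), with a range of −1.18 to −0.74 over the samples left out. With an estimated correlation 0 lists passed camera in each of the 3 comparisons, with 2, 8 and 0 at an unadjusted p under 0.05. With fry 23, 29 and 0 passed, against 11, 16 and 3. The genotype lists numbered 3 to 11 with a clone left out (11 without wild-type clone 2, 5 without knockout clone 1, 7 without knockout clone 2) and 9 with libraries as replicates. Of the 4 time-course lists, 2 passed, but 0 with an estimated correlation, 1 with 500 genes each, and 0 to 3 with a clone left out (1 without wild-type clone 1, 0 without wild-type clone 2 or knockout clone 1). Apart from the fold minimum, which lowers a count by construction, the cause was not tested for any of these changes. Of the named genes' alternatives 7618 stayed on their side of the threshold, 140 passed newly and 95 ended, and of the lists' 1279, 64 and 37. The replicate numbers gave no sign of pairing the libraries. Correlations of same-numbered libraries ran from −0.099 to 0.00388 in the screen and from −0.101 to 0.21 in the clones. Closest to their own number were 0 of 6 and 4 of 12 libraries. With 2 libraries per day the deviations mirror each other, so the screen check rests on few separate values and cannot exclude pairing. As a replicate block the numbers gave 10643, 8318 and 10777 genes in the screen. In the library-level fits they gave 2324, 2001 and 767. All were within 1.5 times of the main counts. RLE size factors changed no count by more than 1.5 times. With each clone set against the mean of the other clones, no chromosome median stood over 0.3 from all genes in any setting run. Depth limits genes near 0 counts, for which only bounds or ratios with intervals are given.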

Other observations

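The comparisons in this part were planned except the Y-linked levels by set, which were chosen after the results were seen. Most imprinted genes rose in the first step of the screen pool. Of 23 imprinted genes 18 rose and 3 fell from day 0 to day 4, over all genes and adjusted over the list alone, with a median log2 change of 1.89 (camera, adjusted p = 6.3e-05; adjusted p = 0.3 with an estimated correlation). Mest rose from 40.7 ± 3.78 to 387 ± 4.60 CPM and Peg10 from 139 ± 1.13 to 721 ± 67.3 CPM (SD, n = 2), while Plagl1 fell by 4.04. From day 4 to day 10, 11 imprinted genes rose and 9 fell, over all genes and adjusted over the list alone, with a median of 0.11 (camera, adjusted p = 0.741; fry, adjusted p = 0.000687). The difference between the steps was not tested. All 20 ribosomal protein genes fell, with a median of −0.65 (camera, adjusted p = 3.43e-05; adjusted p = 0.662 with an estimated correlation), and from day 4 to day 10 16 of them rose, 17 when adjusted over the list alone, with a median of 0.28 (camera, adjusted p = 0.00502; adjusted p = 0.589 with an estimated correlation). Rpl32 fell from 1200 ± 30.0 to 633 ± 15.9 CPM (SD, n = 2). The 7 tested mitochondrially encoded genes rose by day 4, with a median of 0.92 (camera, adjusted p = 0.0121; adjusted p = 0.662 with an estimated correlation), and fell by day 10, with a median of −0.71 (camera, adjusted p = 0.00206; adjusted p = 0.442 with an estimated correlation), all 7 in both steps over all genes and adjusted over the list alone. The cytochrome b gene mt-Cytb went from 3270 ± 288 to 8600 ± 484 and then 5170 ± 414 CPM (SD, n = 2).

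Genes of the Y chromosome were present in the screen pool and absent from the clones. Ddx3y ranged from 60.4 to 109 CPM, Eif2s3y from 63.7 to 120 CPM, Uty from 22.8 to 46.6 CPM and Kdm5d from 1.60 to 5.04 CPM in the 6 screen libraries. In the 12 clone libraries, wild-type and knockout, Ddx3y, Eif2s3y and Uty had 0 counts, and Kdm5d had 0 counts in 11 and 1 count in the remaining library. Xist, the RNA of X inactivation, ranged from 1.19 to 2.67 CPM in the screen and from 6.04 to 17.8 CPM in the clones. Each clone was also compared with the mean of the other clones, chromosome by chromosome. The medians for chromosomes 1 to 19 and X, 80 in all, lay between −0.03 and 0.04 of the median of all genes. A gain or loss shared by all clones would not show in this comparison.

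Wild-type clone 2 also held more transcripts of the two-cell-like state than wild-type clone 1. Of 5 tested genes 4 were higher, 5 when adjusted over the list alone, with a median of 1.73 (camera, adjusted p = 5.03e-05; adjusted p = 0.343 with an estimated correlation), among them Zscan4d at 5.57 ± 1.44 against 1.75 ± 0.448 CPM (SD, n = 3), a member of a family with near-identical copies. Of 18 neural progenitor genes 4 were lower, 10 when adjusted over the list alone, with a median of −0.29 (camera, adjusted p = 0.000393; adjusted p = 0.562 with an estimated correlation).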
